A study of Mus musculus with 2 samples.

How the data were processed

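DNase-seq was carried out on heart tissue from 2 male B6CASTF1/J mice aged 2 months. Per the labels, the samples are biological replicates 1 and 2 of 1 experiment, and their descriptions name separate animals of the same cross, with 1 shared donor identifier. Both form the group heart, and the replicate numbers are those of the labels. For each library the authors deposited 2 peak lists, a list of stretches with a false discovery rate (FDR), a list of footprints and a text describing the files. Per the file descriptions, peaks and FDR stretches were derived from the alignments of that library on mm10 and 1 further file not used here, and footprints from the alignments together with the FDR stretches and 2 further files not used here. Peaks were thus called per library and not on pooled libraries. The aligner, the peak caller, the footprint caller and their thresholds are not given in the sources used here.

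The peak value is the signal in the deposited peak lists, which are narrowPeak files per the file descriptions. What the authors scaled it to is not given in the sources used here. In each library all values were whole multiples of 1 step, 0.00522 in replicate 1 and 0.00407 in replicate 2, with a tolerance of 0.05 of a step. The depth of the libraries is therefore unknown. From the 10th to the 90th percentile the peaks held 83 to 1029 steps in replicate 1 and 88 to 1249 in replicate 2. The values are the authors' own and were used to rank regions within a library. Means and SDs over the 2 animals and single ratios between them are of these unscaled values, and so depend on an unknown scale factor. The comparisons of gene lists and motifs between the animals were made relative to random lists or random sets of regions. A scale factor moves all log2 ratios alike and so cancels there. The matching of random lists and the trend removals used bins of the unscaled mean value, which can depend on it. No alternative rescaled these bins. The FDR values deposited by the authors were all below 0.05, and adjoining stretches were merged into regions with bedtools 2.31.1 at 0.05 and at 0.001. The score column of the deposited footprints held 0.01 throughout and was read as a threshold, so only the positions of footprints were used.

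Each peak of the shorter list overlapped a base with an FDR of 0.001 or lower in the same library. In the longer list 69.5% of the 166078 peaks of replicate 1 and 67.7% of the 156179 peaks of replicate 2 did. The shorter list was taken as the main list. Chromosome lengths and genes came from GRCm38.p6 and GENCODE M21, the same assembly as mm10, for 21 chromosomes. All 341 entries of the gene lists matched a gene symbol, some of them in more than 1 list. Where a symbol had several loci the longest protein-coding one was used.

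Overlap was at least 1 bp. Expected overlap came from 100 random placements of the peaks within their chromosomes, outside assembly gaps, and expected shares of annotation classes from 20 placements. A promoter was the stretch within 1000 bp of any TSS, and a peak's class was that of its centre, in the order promoter, exon, intron and intergenic. Overlapping peaks of both animals were merged into union regions that carried the highest value per animal. A gene had a promoter peak when each animal had a peak within 1000 bp of any of its TSSs. Its promoter value in an animal was that of the highest such peak, so a mean can join different peaks of the 2 animals. The gene lists, 22 of them for cardiomyocyte functions, cell types of the heart, other tissues, housekeeping and imprinting and 1 of all olfactory receptor genes, were fixed before the data were examined, as were the 24 motif consensus sequences. Each list was compared with all other protein-coding genes by a 2-sided Fisher's exact test with Benjamini-Hochberg adjustment over 23 lists and a threshold of 0.05. The CpG comparison used the highest CpG observed-over-expected ratio within 500 bp of a TSS, in 3 tertiles of genes, and an exact test conditional on the tertiles. Distal density was the number of shared regions over 1000 bp from every TSS in the gene body and 20 kb each side. The median of a list was placed among 10000 random lists of the same size matched on gene length in 20 bins, and lists at or beyond percentiles 2.5 and 97.5 were counted. For the difference between the animals, the median log2 ratio over the regions of each gene was placed in the same way among random lists matched on the mean value in 20 bins. The trend removed in 1 alternative was the median ratio of regions in the same class of GC content (10 bins), CpG count (5), peak value (5) and promoter or distal position, and in a further one 6 classes of TSS distance, with bounds at 500, 1000, 5000, 20000 and 100000 bp, took the place of the position. Members of lists were compared by the Kruskal-Wallis statistic with 10000 permutations.

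For motifs, matches on either strand that overlapped a footprint by at least 50% of their length were counted. As random placement the footprints of each peak were shifted together round that peak 100 times, and the 2-sided permutation p was adjusted over the motifs. The reversed, not complemented, consensus served as control, except for KLF_SP, whose reversed consensus holds the same core. Reversal keeps the base composition but not always the CpG count, and some motifs had too few reversed matches for a control. In distal regions, the share with a match within 75 bp of the centre was compared with windows 1000 bp to each side by Fisher's exact test. X and autosomes were described without a test. Text named the 3 genes of each list with the highest mean promoter value and up to 2 without a peak, the 10 highest shared regions, the 10 genes with the most and the 10 with the densest distal regions (at least 10), and the 5 highest regions private to each animal. Some genes that these rules select are not reported here. Errors are SDs over the 2 animals.

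The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, with samtools 1.23.1 for the genome index. Overlaps of peaks were computed with interval code written for this purpose, not with bedtools as planned, and it gave 0 differences from a direct search over 500 intervals. On simulated data, a list of 40 genes with a higher share of open promoters was found in 100% of 100 runs, and an unchanged list was called in 3%. The test conditional on tertiles found a planted list of 20 genes in 100% of 100 runs and called a list open like its tertile in 2%. A list of 20 genes with 2-fold distal density passed percentile 97.5 in 100% of 20 runs, and an unchanged list fell outside the percentiles in 10%. With the trend removed, a shifted list of 20 regions was found in 100% of 20 runs, and a list that followed the trend alone was called in 0%. Footprints planted at CTCF matches gave 2.97-fold over random, and unplanted matches gave 1.02-fold for GATA and 1.27-fold for AP1, the latter with 55 matches. Alternatives changed the peak list, the peak threshold, the overlap, the promoter, locus and motif windows, the annotation, the background, the scaling and the animals that entered, 1 at a time. The text file was not used for values.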

Results

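Open chromatin was mapped by DNase-seq in heart tissue of 2 male mice aged 2 months. DNase-seq sequences the ends that the enzyme DNase I leaves where it cuts DNA, and regulatory DNA free of nucleosomes is cut most often. The animals were B6CASTF1/J mice, the first-generation cross of the C57BL/6J and CAST strains. They form 1 group, heart, with 2 biological replicates, so no comparison between conditions exists. The comparisons are those between the 2 animals, between groups of genes, between kinds of region and sequence motif, and between chromosomes. The shorter of the 2 deposited peak lists held 111462 peaks in replicate 1 and 102390 in replicate 2, with a median width of 200 bp in both. The peaks covered 21.4 Mb and 21.9 Mb. The number of reads behind the libraries is unknown. All peak values were whole multiples of 1 step per library within 0.05 of a step, and the median peak held 203 steps in replicate 1 and 217 in replicate 2. Positions are on mm10 and 1-based.

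The 2 hearts shared most of their open regions, and above all the high ones. Of the peaks of replicate 1, 79.2% overlapped a peak of replicate 2 by at least 1 bp, and 85.6% of the peaks of replicate 2 overlapped a peak of replicate 1. Random placement of the peaks gave means of 1.68% and 1.84% over 100 draws, with highest draws of 1.79% and 1.93%. Sharing rose with the peak value, from 36.1% in the lowest decile of replicate 1 to 99.3% in the highest, and from 44.7% to 99.7% in replicate 2. The union of both lists made 123758 regions, of which 86251 had a peak in both animals. Across these shared regions the Spearman correlation of the values was 0.946 and the Pearson correlation of the log2 values 0.966. Regions are not independent replicates, so no p-value is attached to these correlations. The values were 0.79-fold in replicate 2 relative to replicate 1 in the median. The scale of the values in each library is not stated. The step of the values was lower in replicate 2 too, at 0.00407 against 0.00522 in replicate 1. The 0.79-fold therefore need not be a difference between the animals. After division by the sum over all peaks the median log2 ratio was -0.02, and after division by the median over shared peaks it was 0.03.

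The 10 shared regions with the highest mean value all lay in promoters. The first was at the promoter of Dynlt1b, a dynein light chain gene (chromosome 17, 6429981 to 6430180), with a value of 62.4 ± 11.2 (SD, n = 2). The promoter of Hjurp, a chaperone of the centromeric histone, followed at 51.1 ± 9.8 (chromosome 1, 88277521 to 88277740). A region beside the non-coding gene Gm42418 had 43.2 ± 11.9 (chromosome 17, 39846781 to 39846920). In the unscaled values it was the only 1 of the 10 with the higher value in replicate 2, by 0.57 on the log2 scale. The others were at Dnpep (41.2), Gm21887 on the X chromosome (40.9), Bahcc1 (36.95), Mplkip (36.1), Ankhd1 (36.1), Gatad2a (35.9) and Rragc (35.6). In 3 of the 10 regions most 32-base words also occurred elsewhere in the assembled chromosomes, with 62.1% of the words at Dynlt1b, 82.6% at Gm42418 and 100% at Gm21887. The values of these 3 are therefore uncertain. The other 7 held no such word.

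Promoters held far more peaks than their length gives. On average 30.04% ± 1.2 of the peaks (SD, n = 2) lay within 1000 bp of a transcription start site (TSS), 4.73-fold ± 0.17 over random placement. Exons outside promoters held 4.72% ± 0.35, 1.39-fold over random placement, introns 36.5% ± 0.9 at 0.91-fold, and intergenic DNA 28.7% ± 0.6 at 0.57-fold. Promoter peaks were also higher. The median value in replicate 1 was 1.96 in promoters, 0.94 in introns and 0.88 in intergenic DNA, and in replicate 2 it was 1.82, 0.77 and 0.72. Of 21911 protein-coding genes, 14445 (65.9%) had a promoter peak in both animals, and 590 had one in a single animal.

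Most genes of general functions of the cardiomyocyte, the contracting cell of the heart, had open promoters. Of the sarcomere genes, which encode the contractile apparatus, 23 of 24 had a promoter peak in both animals, against 65.9% of other protein-coding genes (adjusted p = 0.0033, 2-sided Fisher's exact test, Benjamini-Hochberg over 23 lists). The highest sarcomere promoters were those of Myom1, which encodes an M-band protein (24.4 ± 0.4, SD, n = 2), Tpm1, a tropomyosin gene (23.2 ± 1.9), and Cmya5 (8.11 ± 0.47). The named Tpm1 peak lay more than 1000 bp inside the gene, near the TSS of an inner transcript. The median sarcomere promoter had a value of 2.57, at percentile 49.7 of all protein-coding genes, those without a peak included. The exception was Myh7, the slow myosin heavy chain gene, which had no promoter peak in either animal. Of the cardiac transcription factors 21 of 22 had a promoter peak (adjusted p = 0.0070 in the same exact test). They were led by Esrra, a nuclear receptor of mitochondrial metabolism (34.6 ± 5.5), Srf (17.6 ± 3.7) and Klf15 (14.04 ± 2.8), and Hand1 had none. Calcium handling and ion channel genes had 20 of 21 (adjusted p = 0.0070, exact test), with Srl at 30.7 ± 5.8, Camk2d at 16.1 ± 3.7 and the potassium channel gene Kcnj2 at 12.9 ± 1.5, and this call ended with the higher-value 50% of the peaks. All 23 genes of fatty acid oxidation and energy supply had one (adjusted p = 8.57e-04, exact test). Acsl1, which activates long-chain fatty acids, had 21.1 ± 3.3, Acadm 18.8 ± 2.1 and Idh2 13.3 ± 1.4. The median promoter value was 5.49 for cardiac transcription factors (percentile 61.4), 2.24 for calcium handling and ion channel genes (percentile 48.2) and 7.04 for energy genes (percentile 67.0).

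The chambers and the conduction system differed in their counts, without a test of that difference. All 9 ventricular genes had a promoter peak (adjusted p = 0.054, Fisher's exact test), among them Hey2 (17.5 ± 1.9), Lbh (13.3 ± 0.6) and Irx5 (4.77 ± 0.63). Of 11 atrial genes 5 had one (adjusted p = 0.258, exact test), led by Myl4 (13.96 ± 1.57), Pam (8.63 ± 0.51) and Kcna5 (4.35 ± 1.68). Nppa, the gene of atrial natriuretic peptide, and Myl7, the atrial light chain gene, had no promoter peak in either animal. Of the atrial genes 63.6% had one in replicate 1 alone and 45.5% in replicate 2 alone. Against genes of the same CpG tertile, 7.18 ventricular promoters would be open in place of 9 (adjusted p = 0.246, stratified exact test). For atrial genes 6.18 would be open in place of 5 (adjusted p = 0.633, stratified exact test). All 12 conduction system genes had a promoter peak (adjusted p = 0.024, exact test), with Tbx3 at 9.43 ± 1.07, Gja5 at 7.44 ± 2.00 and Etv1 at 6.02 ± 1.09. The conduction call ended with promoters of 500 bp, with the higher-value 50% of the peaks and against genes of the same CpG tertile (adjusted p = 0.816, exact test), of which 91.6% would be open.

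Promoters of the other cell types of the heart varied. All 20 endothelial genes had a promoter peak (adjusted p = 0.0021, Fisher's exact test), led by Sox7 (7.71 ± 0.45), Eng (6.74 ± 1.26) and Esam (6.69 ± 2.22). All 11 smooth muscle and pericyte genes had one (adjusted p = 0.036, exact test), with Kcnj8 at 4.60 ± 0.99, Pdgfrb at 3.14 ± 0.59 and Myocd at 2.37 ± 0.33. This call ended with promoters of 500 bp and with the higher-value 50% of the peaks. Fibroblast genes had 15 of 17 (adjusted p = 0.108, exact test; 100% and adjusted p = 0.0071 in replicate 2 alone, 88.2% and 0.102 in replicate 1 alone), with Gsn at 6.06 ± 1.23, Fbln2 at 4.86 ± 0.86 and Col1a1 at 4.83 ± 0.20. At Esam, Myocd and Col1a1 the highest peaks of the 2 animals did not overlap, so these means join different peaks. Macrophage genes had 10 of 15 (adjusted p = 1, exact test), with Spi1 at 3.07 ± 0.02, Cd68 at 1.99 ± 0.58 and C1qb at 1.62 ± 0.67, while Ptprc and Fcgr1 had none. These CpG-poor promoters compare differently with genes of the same CpG content, since a promoter peak was present in 19.4%, 82.0% and 96.3% of the genes in the 3 CpG tertiles. Against genes of the same tertile, 3.53 macrophage promoters would be open in place of 10 (adjusted p = 9.59e-04, stratified exact test) and 10.95 fibroblast promoters in place of 15 (adjusted p = 0.031). In the same test the sarcomere list had 23 in place of 10.56 (adjusted p = 3.45e-09, exact test) and the endothelial list 20 in place of 12.6 (adjusted p = 1.22e-05).

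Lymphocyte genes had 8 of 16 open promoters (adjusted p = 0.258, Fisher's exact test), led by Lck (5.94), Cd2 (4.48) and Pax5 (2.81), with none at Cd3e and Rag1. Epicardial and mesothelial genes had 7 of 9 (adjusted p = 0.814, exact test), with Tbx18 at 4.38, Aldh1a2 at 2.09 and Wt1 at 2.09. Schwann cell genes had 6 of 10 (adjusted p = 0.814, exact test), with Prx at 13.98 and Pmp22 at 6.28, and none at Sox10. Adipocyte genes had 6 of 11 (adjusted p = 0.637, exact test), with Lipe at 11.9, Fabp4 at 3.22 and Pparg at 2.26, and none at Adipoq and Cidec. The mean of Pparg joins different peaks of the 2 animals. At Lck, Cd2, Pax5, Prx, Pmp22 and Lipe the named peaks lay more than 1000 bp inside the gene, near the TSS of an inner transcript. The lists were not counted with protein-coding transcripts alone.

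Liver, lung epithelium, erythroid and olfactory receptor genes were mostly closed. Of the liver genes 3 of 16 had a promoter peak (adjusted p = 8.57e-04, Fisher's exact test), Apoa2, Ahsg and Apob, all at 0.91 or lower, and Alb and Apoa1 had none. Lung epithelium genes had 2 of 10, Muc1 and Napsa (adjusted p = 0.010, exact test), with none at Sftpc and Sftpb. Erythroid genes had 3 of 12, led by Epor (adjusted p = 0.010, exact test), with none at Hba-a1 and Hbb-bs. All 3 calls ended against genes of the same CpG tertile (adjusted p = 1 each, exact test), of which few were open. Olfactory receptor genes had 9 of 1134, and this call stayed against genes of the same CpG tertile, of which 265.98 would be open (adjusted p = 9.41e-106, exact test). Skeletal muscle genes had 8 of 18 (adjusted p = 0.113, exact test), led by Mylpf (11.5), Actn3 (11.3) and Casq1 (4.34), with none at Myog and Myf5. Neuron genes had 10 of 15 (adjusted p = 1, exact test), led by Dlg4 (3.59), Camk2a (3.21) and Syn1 (2.79), with none at Neurod1 and Neurod6. All 22 housekeeping genes were open (adjusted p = 8.57e-04, exact test), with Rplp0 at 26.6, Actb at 23.7 and Rpl13a at 21.96. Imprinted genes had 16 of 17 (adjusted p = 0.034, exact test), led by Peg3 (9.88), Impact (9.25) and Cdkn1c (8.96), with none at Dlk1. The last 2 calls also ended against the same CpG tertile (adjusted p = 0.633 and 1, exact test), and the imprinted call with promoters of 2500 bp and with the higher-value 50% of the peaks. At Dlg4, Camk2a and Impact the named peaks lay more than 1000 bp inside the gene, near the TSS of an inner transcript. Genes are not independent replicates, and these tests describe the 2 hearts.

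**Figure D1:**
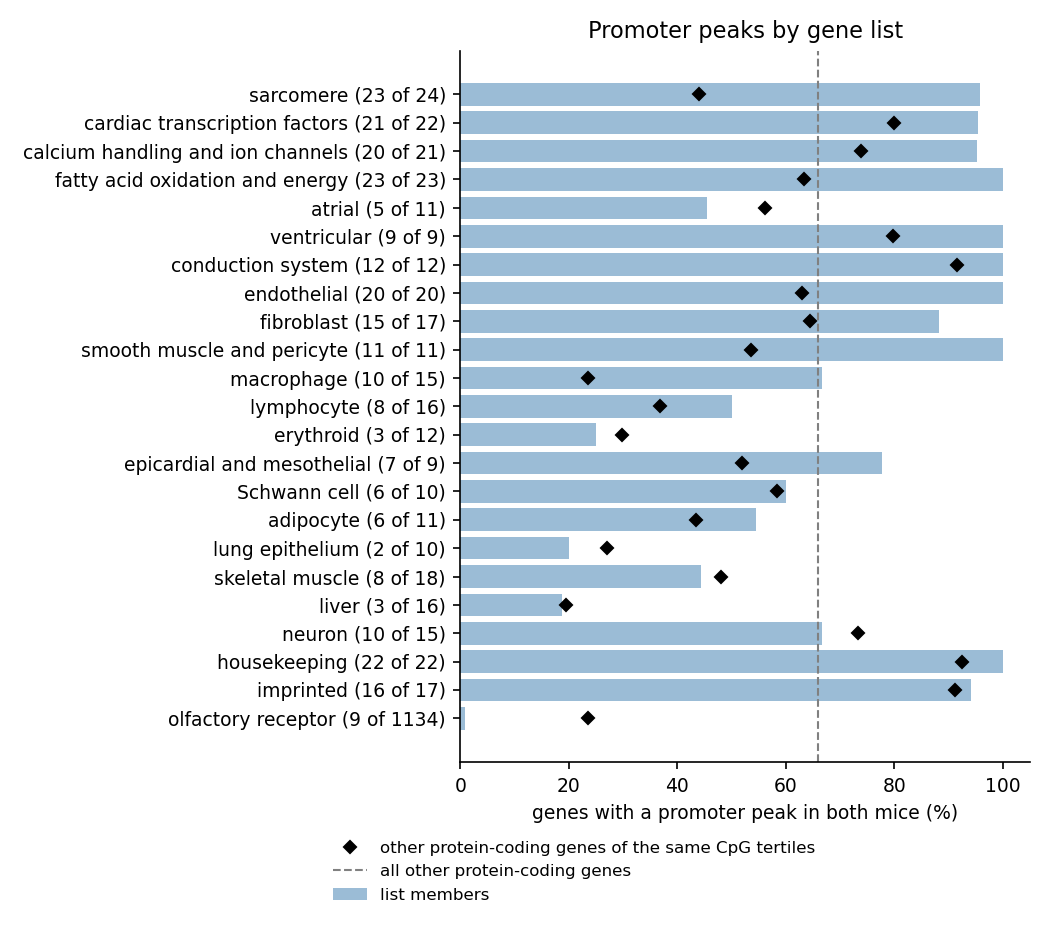
Percentage of genes of each list with a promoter peak in both mice (bars, x axis in %), with the percentage among all other protein-coding genes (dashed line) and among genes of the same CpG tertiles (diamonds). Sarcomere, endothelial and smooth muscle lists lie at 95.8%, 100% and 100%, well to the right of their diamonds at 44.0%, 62.9% and 53.5%.

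Shared distal regions, over 1000 bp from every TSS, were dense around genes of the cardiomyocyte, of vessels and of fibroblasts. Endothelial genes had a median of 8 shared distal regions in the gene body and 20 kb each side, against a median of 2 in random lists of the same locus lengths. None of 10000 random lists reached this (percentile 100). Calcium handling and ion channel genes had 7 against 3 (percentile 99.7) and cardiac transcription factors 6 against 2.5 (percentile 99.7). Sarcomere genes had 5 against 2 (percentile 99.97), fibroblast genes 5 against 2 (percentile 99.8), smooth muscle and pericyte genes 5 against 2 (percentile 98.9) and energy genes 3 against 1 (percentile 97.8). With loci of 100 kb each side, the cardiac transcription factor, energy, fibroblast and smooth muscle lists no longer passed the upper percentile threshold. The fibroblast call also ended with loci of 5 kb, the smooth muscle call with the higher-value 50% of the peaks, and the call of olfactory receptor genes with each of these. The lung epithelium list was newly past the threshold with loci of 100 kb (percentile 98.3). Adipocyte genes, at 3 against 1, reached percentile 95.0, and 97.6 when counted per 10 kb (0.56 against 0.21). The percentile was 87.9 for ventricular, 66.7 for atrial, 64.7 for macrophage, 30.9 for lymphocyte and 25.9 for conduction system genes. It was 83.1 for skeletal muscle, 73.4 for lung epithelium, 71.1 for epicardial, 46.5 for neuron, 43.6 for Schwann cell, 42.4 for erythroid and 29.4 for liver genes. Housekeeping genes, with the highest promoters, lay at percentile 88.7, imprinted genes at 52.1 and olfactory receptor genes at 0.

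The protein-coding genes with the most shared distal regions were Gm20388 (351) and Fgfr2 (132), whose annotated gene models span several megabases. They were followed by Tns1, which encodes the adhesion protein tensin (69), Gse1 (66), Prkce, a protein kinase C gene (57), Camta1 (55), Nav2 (50), Rora (48), Cdh13 (46) and Frmd4a (45). Per 10 kb of locus, Nr1d1, which encodes the circadian repressor REV-ERB alpha, was the densest, with 20 distal regions or 4.22 per 10 kb. Kdm6b (3.44), Gm21887 (3.43), Tmem88 (3.36), Thra (3.22), Btg2 (3.19), Trim35 (3.13), Id3 (3.08), Aurkb (3.04) and Mknk2 (3.03) followed. Thra overlaps Nr1d1 and Tmem88 lies beside Kdm6b, so the loci of each pair overlap.

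**Figure D2:**
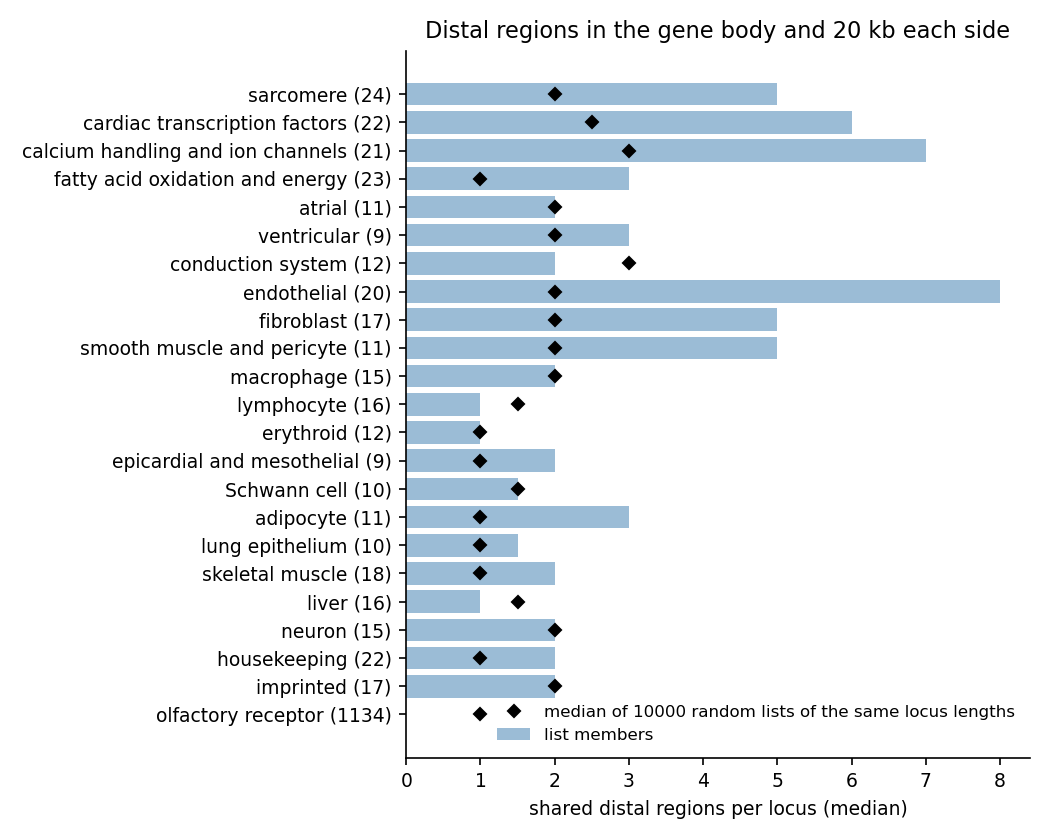
Median number of shared distal regions per locus for each gene list (bars; x axis, regions per gene body with 20 kb each side; members in parentheses) and the median of 10000 random lists matched on locus length (diamonds). Endothelial genes lead with 8 against 2, followed by calcium handling and ion channel genes with 7 against 3.

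Among the gene lists, the 2 hearts differed most clearly in endothelial genes. In shared regions of endothelial genes the median log2 ratio of replicate 2 over replicate 1 was -0.50. It was -0.31 in random lists of the same peak values. The endothelial median lay below all 10000 random lists, and the list stayed below percentile 2.5 under every alternative. Division of the values by their sum or median moves all ratios alike, with the same matching. Those 2 alternatives therefore could not change a list's percentile. Fibroblast genes had -0.47 against -0.32 (percentile 0.36), and the shift was not beyond percentile 2.5 in distal regions alone (percentile 3.06). Lymphocyte genes had -0.16 against -0.32 (percentile 98.6), but this was lost with ranks, in promoter regions alone (percentile 92.5) and in distal regions alone (percentile 81.2). It was kept in 4 of 7 alternatives, at percentiles 99.54 and 99.77 in the trend removals described below. The other 2 were the divisions by the sum and by the median, which could not change it. Cardiac transcription factors had -0.22 (percentile 96.1), and in distal regions alone -0.20 against -0.38 (percentile 99.9). In promoter regions alone they lay on the other side, at -0.22 against -0.15 (percentile 20.6). Macrophage genes had -0.42 (percentile 5.03), and in promoter regions alone -0.54 against -0.13 (percentile 0.04). In distal regions alone they had -0.37 against -0.38 (percentile 55.9), so the shift was absent there. Sarcomere genes, at -0.33, lay within the random lists (percentile 32.3), as did smooth muscle and pericyte genes at -0.37 (percentile 25.1) and housekeeping genes at -0.30 (percentile 38.4). Calcium handling and ion channel genes lay at percentile 62.96, energy genes at 46.5, ventricular genes at 84.8 and conduction system genes at 76.5. Lung epithelium genes lay at 84.96, skeletal muscle genes at 36.1, neuron genes at 40.3 and imprinted genes at 51.3. Atrial, Schwann cell, liver and adipocyte genes lay at percentiles 4.76, 4.86, 5.42 and 7.60, erythroid at 18.2 and epicardial genes at 20.7. Olfactory receptor genes, at -0.42, lay at percentile 0.04, with 106 members that had a region, and within the percentiles in promoter regions alone, in distal regions alone and with the trend below removed. The ratio also depended on the distance to a TSS. Its median was -0.18 within 500 bp and -0.47 beyond 100000 bp, with SDs across regions of 0.36 and 0.38. With the trend on GC content, CpG count, promoter or distal position and peak value removed, an alternative chosen after the data were examined, 19 of 20 endothelial and 14 of 17 fibroblast genes were below the median, against 6 of 24 sarcomere genes. The endothelial list then lay below all random lists. The fibroblast list lay at percentile 5.2 and the sarcomere list at 79.6, both within them. Calcium handling and ion channel genes had 7 of 21 members below the median and lay at percentile 72.6. With 6 classes of TSS distance in place of position, also chosen afterwards, the endothelial and fibroblast lists lay at percentiles 0.03 and 7.24. With 1 animal against 1, no test between the animals is possible.

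**Figure D3:**
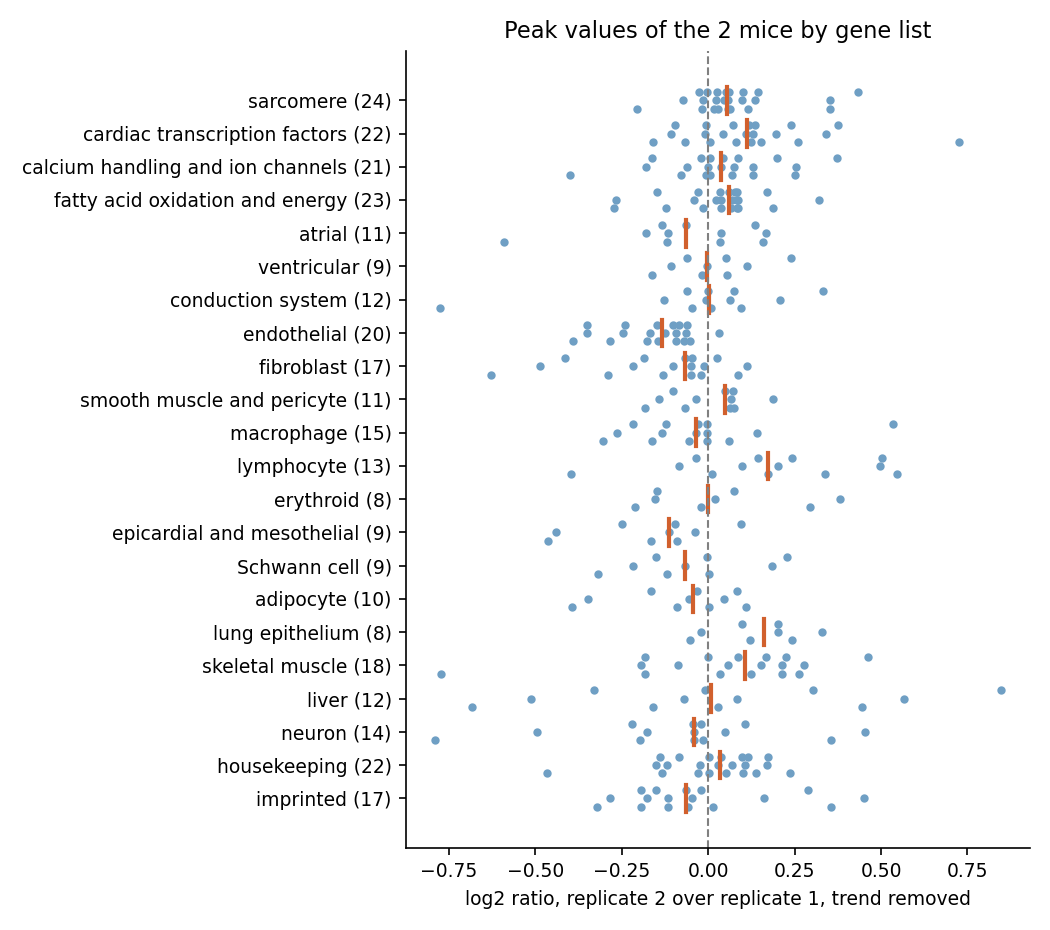
Median log2 ratio of the peak values, replicate 2 over replicate 1, with the trend on GC content, CpG count, promoter or distal position and peak value removed (x axis), for each gene (points) of each list (members with a region in parentheses) and the list's median (orange bars). Of the endothelial genes 19 of 20 lie left of 0, the median of all regions.

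Few regions were private to 1 animal. Of the regions of replicate 1, 4553 (4.16%) had no peak and no enriched region in replicate 2, and 4937 (4.91%) of those of replicate 2 had none in replicate 1. Their median values were low, at 0.43 and 0.31. The highest of replicate 1 lay in an intron of Vgll4, a cofactor of TEAD factors (chromosome 6, 114883301 to 114883480, value 3.54). The next were at the promoter of Anapc16 (2.34), 16902 bp from F730035P03Rik (1.71), and in introns of Bgn (1.64) and Foxo3 (1.56). The highest of replicate 2 lay 6538 bp from the pseudogene Gm2651 (chromosome 6, 3201281 to 3201380, value 1.32), in an intron of Ndst1 (1.20), an exon of Sp9 (1.19), an intron of Gnai2 (1.18) and an intron of Slc48a1 near Hdac7 (1.17).

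Footprints, short stretches protected from DNase I inside open chromatin, numbered 434092 in replicate 1 and 482002 in replicate 2, with a median width of 10 bp. Of them 66.5% and 61.4% lay inside peaks, and 90.7% and 90.2% of the peak regions held at least 1. Inside regions open in both animals, 67.4% of the footprints of replicate 1 overlapped one of replicate 2, against 43.8% after random shifts within the same regions. For replicate 2 the values were 63.5% and 40.6%. With a reciprocal overlap of 50% the excess over random was larger, 3.43-fold and 3.52-fold in place of 1.54-fold and 1.57-fold.

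Consensus matches of several factors lay in footprints more often than by random shifts. Binding of the factors was not measured. Matches to the consensus of CTCF, the insulator protein, lay in footprints in 95.5% of 4791 cases in replicate 1 and 95.9% of 4450 in replicate 2, 3.15-fold ± 0.03 over random shifts (SD, n = 2). NFI matches had 4.39-fold ± 0.15, REST 4.38-fold ± 0.08 with 58 and 64 matches, CRE 2.71-fold ± 0.02, NRF1 2.65-fold ± 0.04, RFX 2.38-fold ± 0.07, ETS 2.38-fold ± 0.02 and YY1 1.69-fold ± 0.17. ERR, the site of Esrra and its relatives, had 1.39-fold ± 0.01, the E-box 1.25-fold ± 0.01 and AP1 1.21-fold ± 0.06. KLF_SP had 2.49-fold ± 0.04. These 12 of 24 motifs passed in both animals (adjusted p = 0.026 in replicate 1 and 0.028 in replicate 2, permutation test, the smallest that 100 shifts give). ERR, E-box and AP1 were above random in distal peaks (1.49-fold, 1.37-fold and 1.26-fold) and not in promoter peaks (0.92-fold, 0.90-fold and 0.98-fold). TEAD and SRF passed in replicate 1 alone (1.07-fold and 1.15-fold). MEF2, PU1 and the steroid receptor site passed in neither, at means of 1.02-fold, 1.22-fold and 1.10-fold. Matches of GATA (0.59-fold), FOX (0.32-fold), MEIS (0.66-fold) and TBX (0.75-fold) lay in footprints less often than by random shifts in both animals, and NKX2 did so in replicate 2 (0.84-fold). The reversed consensus, of the same base composition but not always the same CpG count, was low as well for some motifs. It was less low than the motif for GATA (0.76-fold and 0.70-fold) and FOX (0.83-fold and 0.81-fold), also low for NKX2 (0.86-fold and 0.79-fold) and high for ETS (1.30-fold and 1.36-fold). It was low too for PU1 (0.38-fold and 0.33-fold), TEAD (0.60-fold and 0.54-fold), MEF2 (0.65-fold and 0.70-fold), AP1 (0.77-fold and 0.76-fold), ERR (0.86-fold and 0.78-fold) and CRE (0.86-fold and 0.84-fold), so 1 is not the level of the control for these motifs. Each of these controls passed in replicate 2 alone (adjusted p = 0.043, permutation test). The smallest permutation p that 100 shifts give is 0.0198, and passing depends on how many controls reach it. This call therefore shows no difference between the animals. The control of RFX stood at 1.64-fold and 1.19-fold, on 44 and 51 matches. Reversed matches were too few for a control at CTCF (11 and 14), NFI (7 and 6), NRF1 (3 and 4), YY1 (3 and 5) and REST (0 in both). HNF1, with 1 match and 0 matches, and POU5F1_SOX2, with 0 in both, could not be assessed. Several of these calls depended on the overlap rule. With the whole match inside the footprint MEF2 (0.55-fold and 0.65-fold) and TEAD (0.83-fold and 0.77-fold) were below random in both animals, and PU1 (0.70-fold and 0.56-fold) in replicate 2. With an overlap of 1 bp MEF2 (1.26-fold and 1.30-fold), TEAD (1.17-fold and 1.15-fold), SRF (1.12-fold and 1.20-fold), PU1 (1.18-fold and 1.24-fold) and the steroid receptor site (1.23-fold and 1.29-fold) were above random in both. The whole-match rule ended the ERR call in replicate 2 (1.16-fold, adjusted p = 0.259, permutation test) and the YY1 call in replicate 1 (1.61-fold, adjusted p = 0.053). The YY1 call also ended in distal peaks, with 14 matches in each animal (adjusted p = 0.079 and 0.113, permutation test), while TEAD and PU1 passed there in both animals. The TBX call ended in distal peaks of replicate 1. From the 1 bp rule to the whole-match rule the fold of CTCF rose from 2.27 to 7.01 and that of NFI from 2.41 to 10.9 in replicate 1.

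**Figure D4:**
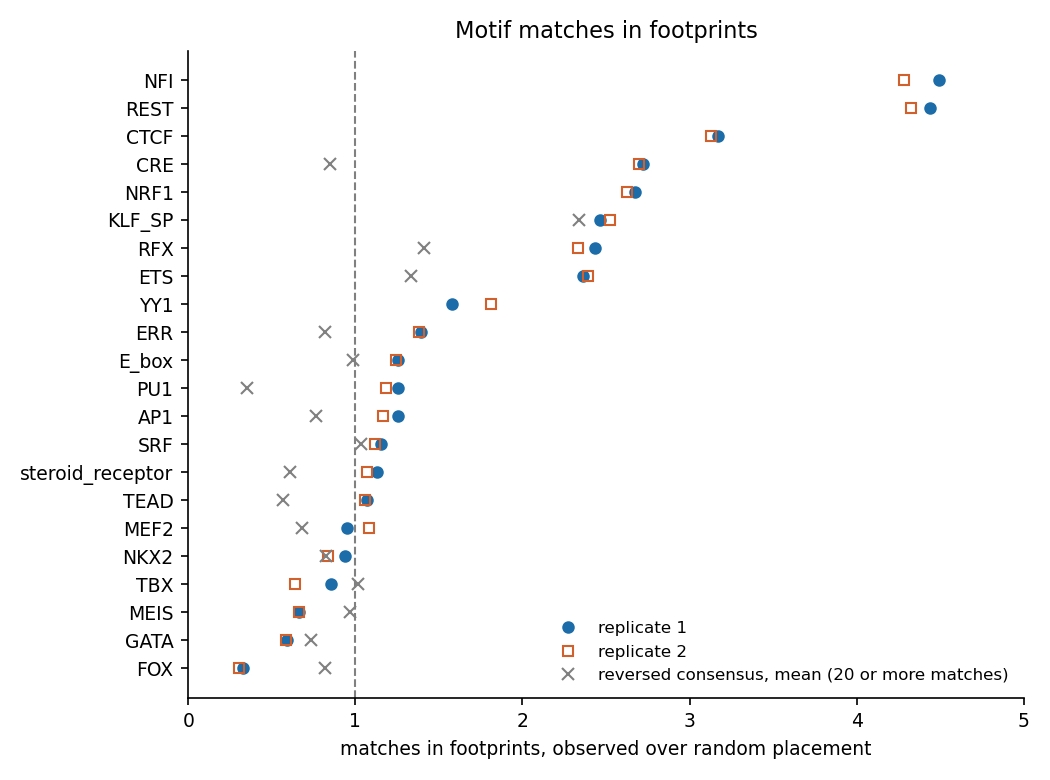
Motif matches in footprints, observed over the mean of 100 random shifts within the peaks (x axis), for replicate 1 (circles), replicate 2 (squares) and the reversed consensus (crosses, where it had 20 or more matches; that of KLF_SP shares its core and is no control). NFI, REST and CTCF lie at 4.39, 4.38 and 3.15, and FOX lies lowest at 0.32.

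The same motifs were counted in distal regions and in windows beside them. The exact tests here took regions and windows as unpaired, and regions are not independent replicates. Their p-values therefore describe these regions and do not measure a spread between animals. Of 59323 shared distal regions, 7.04% had an AP1 match within 75 bp of the centre, against 2.70% of windows 1000 bp away, a 2.60-fold excess. The E-box had 6.13% against 1.94% (3.16-fold), CTCF 5.99% against 0.15% (40.6-fold), and TEAD 4.08% against 2.41% (1.69-fold, adjusted p = 5.35e-80, Fisher's exact test). MEIS was 1.48-fold (adjusted p = 1.55e-16, exact test), NKX2 1.12-fold (adjusted p = 0.0057) and GATA 1.10-fold (adjusted p = 2.26e-06). NFI (11.4-fold), the steroid receptor site (4.01-fold), PU1 (3.90-fold), CRE (3.88-fold), NRF1 (3.54-fold), RFX (2.33-fold) and ETS (2.07-fold) passed the test as well, each in 0.51% of the regions or fewer. KLF_SP was 3.78-fold. The reversed consensus keeps the base composition but not always the CpG count. It was also above the windows for 4 motifs, E-box (2.00-fold), CRE (1.5-fold), ETS (1.36-fold) and MEIS (1.23-fold), and reached 2.11-fold for RFX (adjusted p = 0.051, exact test). It was below them for MEF2 (0.17-fold), GATA (0.65-fold), TEAD (0.73-fold), FOX (0.75-fold) and SRF (0.84-fold), so the windows differ from the regions in composition. REST matched 29 distal regions and 0 of the windows. MEF2 (0.98-fold), SRF (1.12-fold), ERR (0.98-fold), FOX (1.03-fold) and YY1 (1.5-fold) did not pass, and TBX was lower, at 0.65-fold. The windows had a lower GC content than the regions, with medians of 46.7% and 53.3%. Against genome windows of matched GC content, the AT-rich MEF2 site was 5.03-fold (adjusted p = 2.26e-180, exact test), FOX 1.49-fold, SRF 1.28-fold (adjusted p = 3.47e-04) and ERR 1.21-fold (adjusted p = 0.015), so 4 of the motifs that did not pass against the windows beside the regions passed here. GC matching also moved CTCF to 87.9-fold, ETS to 3.59-fold and CRE to 2.55-fold, and CTCF was 64.6-fold within 50 bp and 20.6-fold within 150 bp of the centre. Against the windows beside the regions MEF2 was below them within 50 bp (0.92-fold, adjusted p = 0.048, exact test), and FOX (1.09-fold, adjusted p = 7.50e-04) and SRF (1.11-fold, adjusted p = 0.0089) passed within 150 bp.

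The X chromosome had fewer and lower peaks than the autosomes in both males. It held 16.0 peaks per Mb in replicate 1 and 14.1 in replicate 2, while the autosomes had medians of 46.8 and 43.1 and minima of 34.1 and 30.7. The median value of shared regions was 0.76 on X, against 1.19 as the autosome median and 1.04 as the lowest autosome, a ratio of 0.64. In promoter regions alone the ratio was 0.60 and in distal regions alone 0.61. Of the X-linked protein-coding genes 48.5% had a promoter peak in both animals, against a median of 69.0% and a minimum of 54.9% on autosomes.

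**Figure D5:**
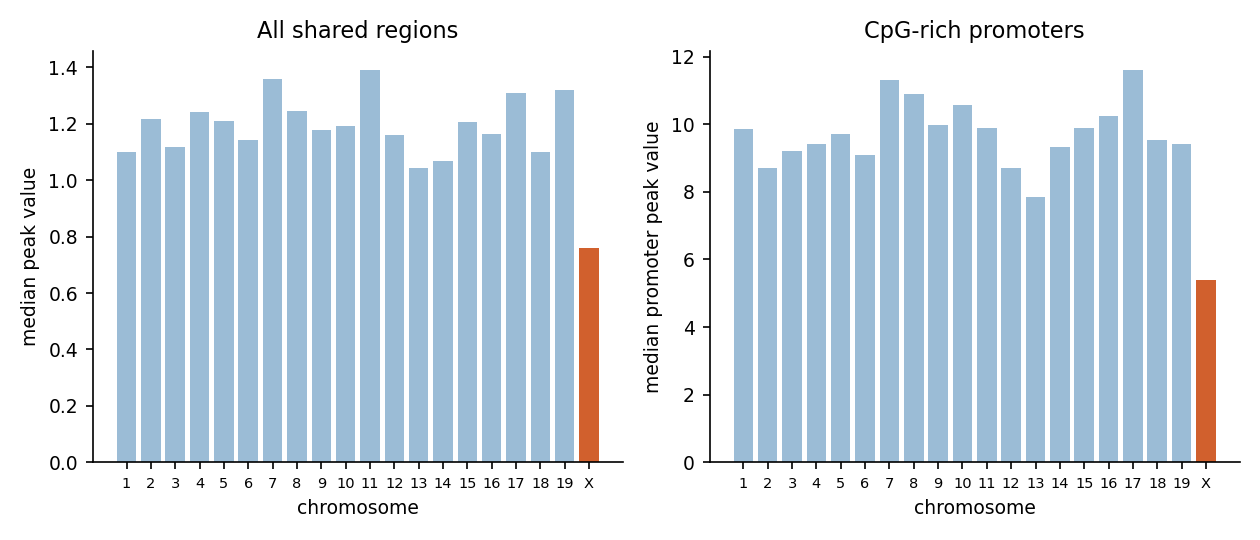
Median peak value per chromosome (bars, mean of the 2 mice; X in orange) of all shared regions (left) and of the promoters of protein-coding genes in the highest CpG tertile (right). X lies at 0.76 and 5.39, below the lowest autosome at 1.04 and 7.86.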

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

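The tests of sequence trend and of a shared loss of cell types below were chosen after the results they bear on had been seen. Those of X and of repeated words were set beforehand. The threshold for endothelial members was too, but its count rests on a trend removal chosen after the data were examined.

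Footprints were also present outside the peaks, in data that the comparisons of peaks leave out. Outside every peak of either list lay 55551 footprints of replicate 1 (12.8%) and 86965 of replicate 2 (18.0%). Of all footprints 99.2% and 98.8% lay inside stretches with an FDR of 0.05 or lower, so most of these lay in such stretches too. Footprints were derived with the help of the FDR stretches, so these shares may follow from the calling and are no support for the footprints. Among stretches of 150 bp or more with an FDR of 0.001 or lower, 1 of 80871 in replicate 1 and 11 of 72141 in replicate 2 held no listed peak, and none of them overlapped a peak of the other animal.

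Endothelial regions were lower in replicate 2 relative to random lists. A bias with GC content, CpG count, TSS distance or peak height as the whole cause is argued against, since the list lay at percentile 0.03 among 10000 random lists with that trend removed in 6 classes of TSS distance. A smaller share of every cell type but cardiomyocytes cannot be told apart from a difference of single cell types. The members of 7 lists of other cell types differed (p = 0.0090, permutation test of the Kruskal-Wallis statistic), but without the lymphocyte list the test did not pass (p = 0.330, permutation test). The lymphocyte list lay at percentile 99.77, with 8 of 16 promoters open. The other lists lay at percentiles 2.63 (epicardial), 7.10 (macrophage), 7.24 (fibroblast), 11.3 (Schwann cell), 19.3 (adipocyte) and 40.1 (smooth muscle and pericyte). A smaller share of endothelial cells alone cannot be told apart either. That 19 of 20 members lay below the median largely restates the pattern, and the files hold no cell counts. For fibroblast genes the sequence trend cannot be told apart from a difference of their own, since the list's median was -0.47 against -0.32 in random lists before and -0.06 against 0.01 after the trend was removed, at percentile 7.24. The design gives no group to which a biological difference between the animals could be tied.

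The lower values on X were set against 2 explanations. Repeated sequence on X is argued against, because regions whose 32-base words each occur once in the chromosomes had a ratio of 0.65 to autosomes, with medians of 0.78 and 1.20. One copy of X per cell, which males carry, stays open as the cause. CpG-rich promoters of X had a ratio of 0.55 to the autosome median, within the range set beforehand for this cause. They lay below all 19 autosomes (5.39 against a lowest of 7.86). A peak was present at 91.0% of these X promoters and at 95.1% to 98.6% on autosomes, so few low values were missing. Both animals were male, so no comparison by sex was possible.

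The highest shared regions included repeated sequence. Reads from other copies in the assembled chromosomes cannot be told apart from true height as the source of these regions, since 3 of the 10 had 50% or more of their words elsewhere, against 0.73% of 1926 autosomal regions drawn at random. The other 7 had none, and copies missing from the assembly were not searched.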

How the results depend on the processing

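The trend removals, the higher-value regions for distal minus promoter regions and the footprints of the longer list were alternatives chosen after the data were examined. The planned stricter footprint threshold was not run, because the footprint column held 1 value, and leaving out an animal is not possible where both are compared. No paired analysis was possible because there is 1 group. Peaks per animal averaged 53463 for the higher-value 50% and 161128.5 in the longer list. Sharing was 72.6% with 50% reciprocal overlap, 76.1% with centres within 75 bp and 89.1% between equal numbers of the highest peaks, and correlation 0.966 (Pearson) and 0.916 (higher-value 50%). The promoter share was 23.7% within 500 bp, 39.9% within 2500 bp and 23.5% with protein-coding transcripts only. With loci of 100 kb each side 5 lists in place of 8 were beyond the percentiles for distal density, with 4 lost and lung epithelium new, and in distal regions alone 2 in place of 4 for the difference between the animals. The median log2 ratio of the animals was -0.016 after scaling by the sum and reversed to 0.027 by the median. Unscaled, it was -0.19 in promoter and -0.40 in distal regions. Its sign depends on the scaling, so the comparisons of lists and motifs rest on differences between regions. Distal minus promoter was -0.21, and -0.22 in the higher-value 50%. The longer list held 81.1% of footprints, and their sharing was 3.47-fold over random with 50% reciprocal overlap. In promoter peaks alone ERR, AP1 and E-box matches lay at 0.92-fold, 0.98-fold and 0.90-fold, on the other side of 1 but without passing a test. X over autosomes was 0.60 in promoters and 0.61 in distal regions, and 0.64 to 0.65 without either animal. The scaling acts by construction, and otherwise the cause was not tested. Of the comparisons of whole results 35 kept their value or call, 20 moved and 1 reversed. Of those of single lists and motifs 488 kept theirs, 100 moved and 3 reversed, with 25 newly past the threshold and 17 no longer past it. Most that moved were percentiles of distal density, of which 82 moved and 33 kept their value. For the difference between the animals by list, the divisions by the sum and by the median kept the calls by construction. The unknown depth leaves open how many weak regions of 1 animal were missed in the other.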

Other observations

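The tests in this part were chosen after the data were examined. The 2 hearts also differed by motif. With the trend on GC content, CpG count and value removed within distal regions, the 3554 shared distal regions with a CTCF match had a median log2 ratio of 0.12 (replicate 2 over replicate 1), above all 1000 random sets of the same size, whose highest was 0.02. Regions with TBX (0.06), ERR (0.05) and MEF2 (0.02) matches lay at percentiles 100, 99.5 and 99.1. The 4175 regions with an AP1 match had -0.06, below all 1000 random sets, and FOX (-0.03), CRE (-0.06) and KLF_SP (-0.05) lay at percentiles 0.1, 0.9 and 1.3. With 6 classes of TSS distance added to the trend CTCF (0.12), AP1 (-0.06), TBX (0.06), MEF2 (0.03), ERR (0.04), FOX (-0.02) and CRE (-0.05) stayed beyond the percentile thresholds, and KLF_SP lay at percentile 5.2. Without these classes GATA regions, at percentile 37.9, TEAD regions, at 27, and PU1 regions, at 10.4, lay within the random sets. The median value was 1.20 in CTCF regions and 1.00 in all distal regions, but it was also above that in KLF_SP (1.49), CRE (1.18) and AP1 (1.05) regions, whose ratio lay on the other side, and MEF2 regions had 0.94.

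Within the loci of single gene lists the motifs were counted too. MEF2 matches were in 5.30% of 132 distal regions of sarcomere genes and 2.36% of other distal regions (p = 0.038, Fisher's exact test). They were in 0 of 161 distal regions of endothelial genes (p = 0.036, exact test), while GATA matches were in 11.2% of these against 6.24% (p = 0.020) and in 11.9% of 101 regions of fibroblast genes against 6.25% (p = 0.035). TBX matches were in 2.60% of 192 regions of cardiac transcription factor genes against 0.66% (p = 0.0099, exact test), ERR matches in 2.08% against 0.65% (p = 0.039) and FOX matches in none against 2.01% (p = 0.036). In 192 regions of calcium handling and ion channel genes TEAD matches were in 7.29% against 4.07% (p = 0.041, exact test) and AP1 matches in 3.13% against 7.05% (p = 0.033). Some p-values under 0.05 arise by chance over this number of pairs, and how many was not tested. None of the 152 pairs of list and motif passed the adjustment (adjusted p = 0.684 for each of these, exact test).

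With the trend removed by promoter or distal position, other lists also leaned one way between the animals. Lymphocyte genes had 3 of 13 members below the median of all regions and lay at percentile 99.54 among random lists. Cardiac transcription factor genes had 6 of 22 below (percentile 98.97). Skeletal muscle genes had 6 of 18 below (percentile 96.96) and lung epithelium genes 2 of 8 (percentile 97.1), short of the upper threshold. Macrophage genes had 12 of 15 below (percentile 19.9), 3 of them neighbouring genes with the same value of -0.0034, epicardial genes 8 of 9 (percentile 7.04) and imprinted genes 12 of 17 (percentile 5.16), all above the lower threshold at percentile 2.5. With 6 classes of TSS distance in the trend imprinted genes passed it (percentile 2.44), epicardial genes reached 2.63 and macrophage genes 7.10, and cardiac transcription factor genes stayed beyond the upper one (percentile 99.13).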
